A study of Mus musculus with 2 samples.

How the data were processed

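The 2 libraries came from E14 cells, an established mouse embryonic stem cell line grown on gelatin with leukaemia inhibitory factor, the cytokine that keeps such cells undifferentiated. One library was made from chromatin precipitated with an antibody against NcoA3, a nuclear receptor coactivator, and the other is its control. Per the labels, 600 µg of chromatin and 8 to 10 µg of antibody went into the precipitation, and single-end libraries were amplified for 14 cycles and sequenced on a GAII instrument. The control is called input in its title and description, while its antibody field reads IgG. It is called input here, and the labels leave open which it was.

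The aligned reads were deposited as 1 line per read with its start, end and strand on mm8, per the submitters' processing notes. The aligner is not given in the sources used here. Every read spanned 35 bp, and no start position and strand occurred more than once in either library, so repeated reads were absent from the files as deposited by the authors. The ChIP library held 11509916 reads, which was 95.9% of the 12003106 tags its peak caller header counts. The control held 15125180 reads, or 82.5% of the 18332357 tags in that header.

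The authors called peaks with MACS 1.4.1, per the file headers, from 1 ChIP library against 1 control without pooling. The header gives a p-value limit of 1e-05, an effective genome size of 1.87e+09, a band width of 300 bp, a model fold of 10 to 30, and at most 2 tags per position. It also says that the smaller library was scaled towards the larger one and that d, the tag distance used, was 200 bp. The deposited list gives each peak a tag count, which is a whole-number count of ChIP tags. It gives a score, which the authors' caller wrote as 10 times the negative log10 of the p-value. It gives a fold enrichment, the ratio of ChIP tags at the summit to the caller's local background, per the file headers. It also gives an empirical false discovery rate in percent, which the authors' caller derives from calling peaks with the libraries swapped. Peak positions count from 1, since each stated length equals end minus start plus 1.

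From these files, reads were counted per region with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The distance between strands was taken as the shift from 36 to 400 bp with the most pairs of plus and minus 5′ ends on the autosomes, after an 11 bp running mean. In the ChIP library a maximum at 67 bp was nearly as high as that at 132 bp, and counting with 5′ ends not moved was an alternative. Each 5′ end was then moved inward by 66 bp in the ChIP library and 75 bp in the control, and counted once where it fell within a peak as the authors drew it. Libraries were scaled by their reads on chromosomes 1 to 19, X and Y, so that 0.761 ChIP reads per control read were expected without enrichment. Fold values per peak had a pseudocount of 1 read in each library, while ratios with intervals had none. Per peak, an exact two-sided binomial test set the ChIP reads against all reads of both libraries in the peak, with Benjamini-Hochberg adjustment over 2017 peaks and a limit of 0.05. With 1 library per group, this test compares these 2 libraries and not the conditions, and the difference has no replicate check. The authors chose the peaks on the same reads, so the test describes their list and is not independent evidence.

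Background came from 100 random sets of regions with the widths and chromosomes of the peaks, at least 1 kb from any peak and in 10 kb bins with 10 or more control reads. Peaks per chromosome were tested with an exact binomial test against each chromosome's share of control reads. Enriched 1 kb bins needed at least 10 reads, 4-fold enrichment and an adjusted p of 0.05 or less in a one-sided exact binomial test. Read density along chromosomes was the median of 10 kb bins with 10 or more control reads in each 1 Mb, over the autosome median. Runs of 5 or more usable 1 Mb blocks of the autosomes were then listed from a running median of 3 blocks in the ChIP library. That running median had to be at 1.25 or above, or at 0.75 or below. On chromosome 8 the run at 75000001 to 111000000 was examined at first, and the run at 53000001 to 73000000 was joined to it after values for the former had been seen. Intervals are 95% exact (Clopper-Pearson, conditional for ratios) and cover counting error only, because reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 reads, which is 0.261 RPM in the ChIP library and 0.198 RPM in the control.

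The tests were checked on simulated counts with 200 changed regions. For the peak test over 2017 peaks, 5 of 67 true 2-fold changes, 33 of 67 true 4-fold changes and 58 of 66 true 8-fold changes were called, with 0 false calls among 1817. For the bin test over 55457 bins, 0 of 67, 22 of 67 and 55 of 66 were called at the same folds, with 4 false calls among 55257. Those bins took their means from the control on a single chromosome, while the real bin test covered 150057 bins. Both simulated libraries shared their means, without the regional differences in coverage of the real ones. The false calls therefore cover counting error only.

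Before the data were examined, the peaks to name were fixed as the 10 with the highest authors' score. Gene lists, distances to transcription start sites and the nuclear receptor motif had also been planned, for use only with an mm8 annotation or sequence. The gene table at hand is of GRCm38, and the peak list names no genes, so these parts were not run and peaks are given by mm8 position without a gene name. Alternatives covered the read shift, the interval, the scaling, the pseudocount, the fold limit and stricter parts of the list. Keeping 1 read per position could not change a value, since the deposited reads already had 1 per position.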

Results

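NcoA3-bound chromatin from E14 mouse embryonic stem cells was profiled by ChIP-seq, in which DNA bound by a protein is precipitated with an antibody and sequenced. The data consisted of 1 NcoA3 ChIP library, 1 control library called input, and the authors' list of 2017 peaks. The ChIP library held 11509916 reads and the control 15125180, of which 0.0342% and 0.0445% were mitochondrial. Each group had 1 library, so no difference below has a replicate check, and its intervals cover counting error only. Pairs of reads on opposite strands were most frequent at 132 bp in the ChIP library (1.18 times those at 351 to 400 bp) and at 150 bp in the control (1.59 times), after smoothing. In the ChIP library the maximum at 67 bp was nearly as high (1.16 times), so its strand offset is poorly defined.

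The first comparison described how far the authors' peaks stood above the control. The authors had chosen these peaks for high ChIP signal over the control on the same reads. Higher values in them than in random regions followed in large part from that choice, and are not independent evidence of NcoA3 binding. The authors' empirical false discovery rate was 100% for 2014 of the 2017 peaks. In the authors' deposited table, peaks covered 1471533 bp in total and had a median length of 613 bp. The tag count per peak ranged from 13 to 1306 with a median of 15, and 598 peaks sat at the lowest count of 13. Reads in peaks made up 0.385% of the ChIP library (44318 reads; interval 0.382% to 0.389%) and 0.107% of the control (16108 reads; interval 0.105% to 0.108%). The peaks together were therefore 3.62-fold higher in the ChIP library (interval 3.55 to 3.68). In 100 sets of random regions of the same widths and chromosomes, the same ratio had a mean of 0.982 and ranged from 0.942 to 1.03. Of the 2017 peaks, 1923 were higher in the ChIP library by the exact binomial test after Benjamini-Hochberg adjustment, 0 were lower and 94 did not pass. The unadjusted count at p under 0.05 was 1924. In 10 random sets that were tested the same way, at most 7 regions were called higher. Random sets held a mean of 0.0612% of ChIP reads against 0.385% in peaks, so few of their regions had enough reads to pass. This count therefore does not show that the calls are specific to the peaks. The fold was 2 or more at 1955 peaks, 4 or more at 961 and 8 or more at 194. At 40 peaks the control held 0 reads. They had 11 to 17 ChIP reads and, with the pseudocount of 1 read, are among the 194 at 8-fold or more. Had the control held the floor of 3 reads per peak, their ratios would have been 4.82 to 7.45. These values leave out the counting error of the ChIP reads, so they are not lower bounds of the ratio. Scaling each peak by the ratio of the libraries in the 100 kb around it gave 1488 peaks that were higher, a setting chosen after the data were seen.

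The strongest sites lay on 9 chromosomes. The top peak by the authors' deposited score spanned positions 59911210 to 59912719 of chromosome 14 on mm8, with its summit at 59912176. It held 173 ChIP reads and 9 control reads, which was 15.04 RPM (reads per 1e+06 reads) against 0.595 RPM and a 25.3-fold ratio (interval 13.0 to 56.2). Its adjusted p in the exact binomial test was 5.89e-48. The peak that ranked next, at 55496218 to 55497426 of chromosome 4, held 118 ChIP and 8 control reads, a 19.4-fold ratio (interval 9.52 to 45.9). The peak at 122305873 to 122308436 of chromosome 6 was the widest of the 10 at 2564 bp and was 17.3-fold higher (interval 9.14 to 37.0), with 132 ChIP and 10 control reads. The peak at 77335524 to 77337762 of chromosome 1 was 12.2-fold higher (interval 6.36 to 26.3).

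The other 6 of the 10 were between 5.37-fold and 9.09-fold higher. They lay at 58077074 to 58078538 of chromosome 9, 135483347 to 135485057 of chromosome 3 and 87390210 to 87391649 of chromosome 12. The remainder lay at 146321957 to 146323522 of chromosome 2, 67654312 to 67655644 of chromosome 10 and 13069525 to 13070856 of chromosome 1. The intervals of these 6 ratios overlapped one another, so the order of their ratios is uncertain. Ranks by the authors' score are a different measure, on which these intervals do not bear. The interval of the top peak (13.0 to 56.2) lay above those of the peaks on chromosome 9 (4.33 to 11.7), chromosome 3 (3.81 to 10.9), chromosome 12 (4.29 to 11.6) and chromosome 2 (3.38 to 8.88). All 10 passed the exact binomial test, with the largest adjusted p at 6.06e-13. In the authors' deposited table, their fold over local background ranged from 11.67 to 46.04. The empirical false discovery rate there was 0% for the peak on chromosome 14, 50% on chromosome 4 and 75% on chromosome 9. It was 100% for the rest of the 10.

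**Figure D1:**
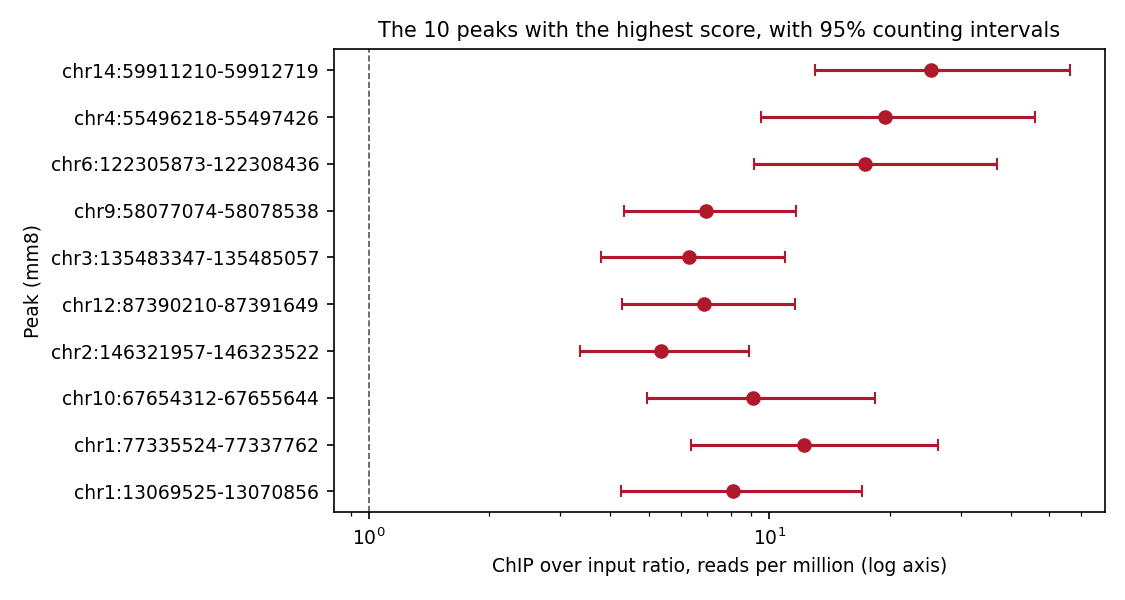
Ratio of RPM in the ChIP library to the control (log axis) at the 10 peaks with the highest authors' score, named by mm8 position; points are ratios, bars are 95% counting intervals and the dashed line marks a ratio of 1. All 10 intervals lie above 1, and the peak on chromosome 14 has the highest ratio at 25.3.

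Peaks were next divided into 4 quartiles by the authors' score, to ask whether weaker sites stood above the control as clearly as strong ones. The median fold was 4.51 in the strongest quartile, 3.94 in the second and the third, and 3.28 in the weakest. The pooled ratio was 3.63 in the strongest quartile, 3.53 in the second, 4.25 in the third and 3.22 in the weakest. Without the 26 peaks of 50 or more control reads, a setting chosen after the data were seen, it was 4.87 (interval 4.71 to 5.03), 4.09 (interval 3.92 to 4.28), 4.50 (interval 4.29 to 4.73) and 3.52. The place of the strongest quartile thus depended on those peaks, while the third stayed above the second and the weakest stayed lowest. By the exact binomial test, 502 of 504 peaks in the strongest quartile, 494 of 504 in the second, 487 of 504 in the third and 440 of 505 in the weakest were higher in the ChIP library. With each peak scaled by the 100 kb around it, the counts were 479, 374, 344 and 291 in the same order, and the pooled ratios 3.32, 3.08, 3.50 and 2.93. The surroundings of the weaker peaks had a raised ratio of the libraries before any peak was counted: its median over the whole-library ratio was 1.23 in the second quartile, 1.30 in the third and 1.20 in the weakest, against 0.985 in the strongest. Within 100 bp of the summit the ChIP signal was 8.71 times that beyond 1.5 kb in the strongest quartile and 4.89 times in the weakest. The control rose in the same places, by 1.78 times in the strongest quartile and 1.07 times in the third. The caller had placed the summits on the ChIP reads, so the ChIP rise there follows in part from that choice. Median peak length fell from 924.5 bp in the strongest quartile to 593.0 bp in the weakest.

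**Figure D2:**
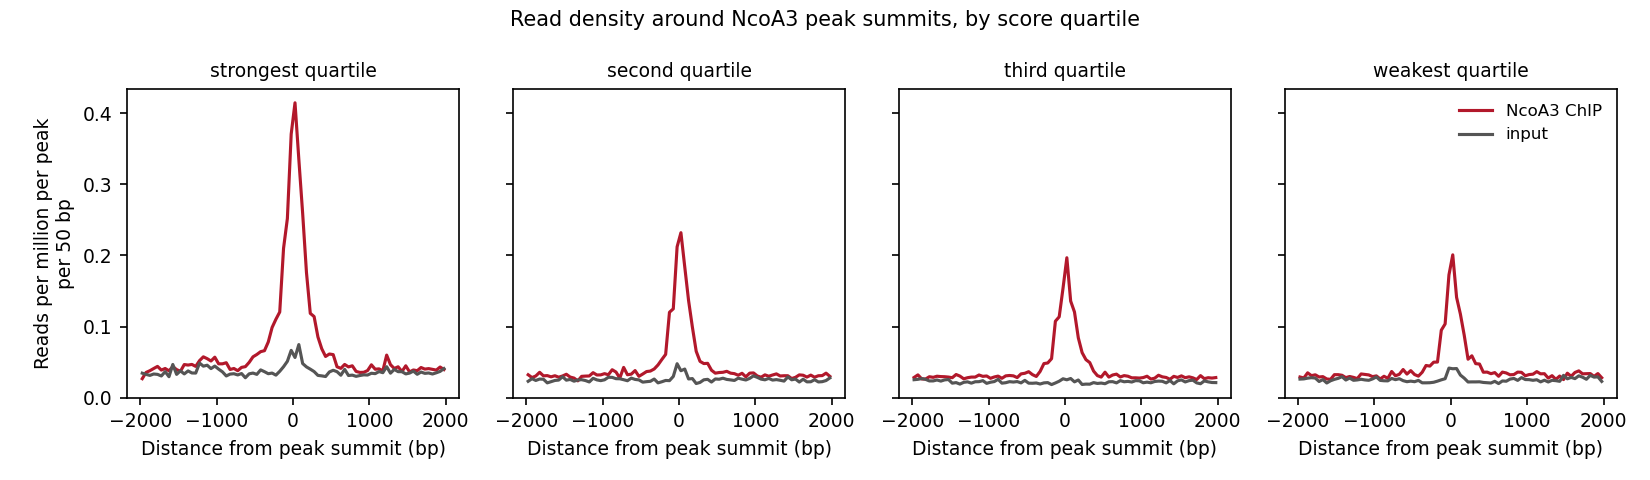
Mean RPM per peak in 50 bp steps from 2 kb upstream to 2 kb downstream of the summit, for the ChIP library (red) and the control (grey), in 4 panels by quartile of the authors' score. The ChIP library peaks at the summit in every quartile, from 8.71 times its edge level in the strongest to 4.89 times in the weakest.

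A small group of peaks had many reads in both libraries. The 26 peaks with 50 or more control reads held 9.62% of all ChIP reads in peaks and 24.5% of all control reads in peaks, and 13 of them were in the strongest quartile. Their ratios ranged from 1.17 to 2.33. This group and the peaks named from it were chosen after their values were seen. The peak with the most reads, at 98466910 to 98468297 of chromosome 2, held 677 ChIP and 682 control reads, a 1.30-fold ratio (interval 1.17 to 1.45). The authors' deposited table counts 1306 tags in it with up to 2 per position, so many were absent from the deposited reads, and how this altered the ratio was not tested. The pair of peaks beside it, from 98464306 to 98466475, had ratios of 1.27 and 1.28. The peak at 3035547 to 3036757 of chromosome 9 had a ratio of 1.17 and did not pass the exact binomial test, with an adjusted p of 0.0527. Without these 26 peaks the pooled ratio was 4.33.

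The distribution of peaks over chromosomes was compared with that of control reads. Chromosome 8 held 278 peaks where its control reads predicted 127.3, a ratio of 2.18 (interval 1.95 to 2.43; adjusted p = 3.26e-32, exact binomial test over 21 chromosomes). No other chromosome passed the test with more peaks than predicted. Chromosome X held 22 peaks against 45.7 predicted (ratio 0.481, adjusted p = 0.000887, exact binomial test), and chromosome 7 held 71 against 114.4 (ratio 0.621, adjusted p = 0.000116, exact binomial test). Chromosome 11 (ratio 0.735) and chromosome 5 (ratio 0.787) also held fewer, with adjusted p of 0.00975 and 0.0460 in the exact binomial test. Chromosome Y held 0 peaks. With chromosome lengths in place of control reads, only 3 chromosomes passed, with chromosome 8 again the sole one above its prediction and chromosomes X and 7 below. In the stricter part of the list, a setting chosen after the data were seen, chromosomes 8 and 7 passed, and chromosomes X, 11 and 5 did not. By quartile, chromosome 8 was 1.29-fold above its control reads in the strongest quartile (interval 0.935 to 1.72), 2.17-fold in the second, 2.64-fold in the third and 2.64-fold in the weakest.

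**Figure D3:**
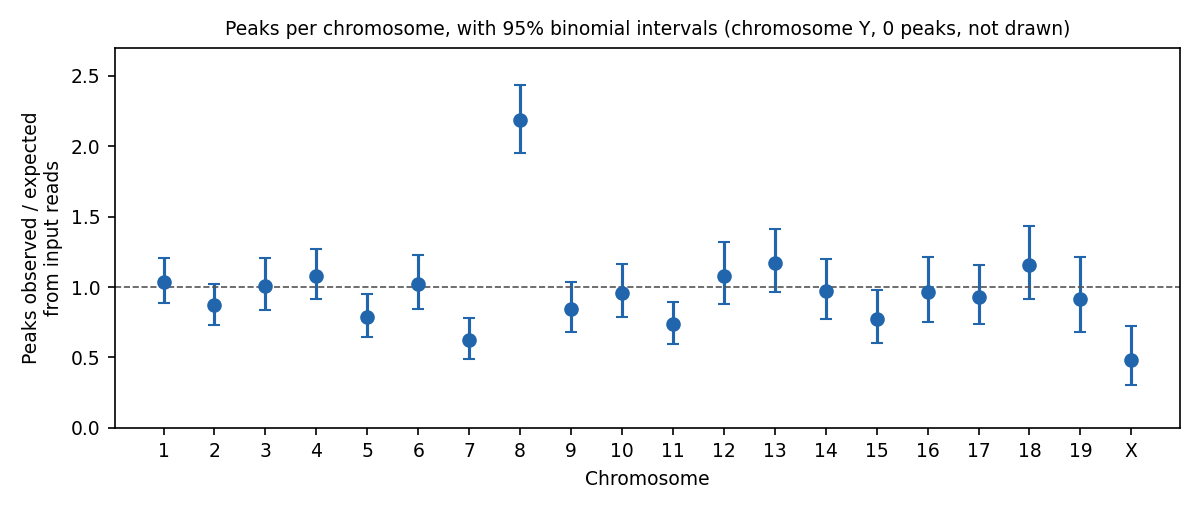
Number of peaks on each chromosome with a peak over the number its control reads predict (chromosome Y, with 0 peaks, is not drawn); points are ratios, bars are 95% exact binomial intervals and the dashed line marks 1. Chromosome 8 stands at 2.18, and chromosomes X and 7 lie lowest of those drawn at 0.481 and 0.621.

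Read density per covered kb was compared between chromosomes, as a guide to copy number in these cells. In the control, chromosome 8 stood at 1.22 times the autosome median and in the ChIP library outside peaks at 1.17 times. Chromosome X stood at 0.429 times in the control and 0.581 times in the ChIP library. Chromosome 11 was at 1.22 times in the control but 1.01 times in the ChIP library. A low run of 1 Mb blocks lay within 6000001 to 14000000 of chromosome 7 and held 3 peaks. Its median density was 0.707 times the autosome median in the ChIP library and 0.625 times in the control. Chromosome 8 held a dense stretch at 53000001 to 111000000, found after the data were seen, in which density outside peaks was 1.45 times that of the other autosomes in both libraries. The rise was less even in the control: in the first part, at 53000001 to 73000000, it stood at 1.10 times against 1.49 in the ChIP library, and in the second, at 75000001 to 111000000, at 1.55 times against 1.45. The first part held 110 peaks and the second 123. The stretch held 233 of the chromosome's peaks, or 4.16 per Mb, against 0.777 per Mb on the other autosomes, a 5.36-fold difference (interval 4.65 to 6.15). The rest of chromosome 8 held 45 peaks, or 0.666 per Mb (ratio 0.857, interval 0.623 to 1.15). Leaving out chromosome 8, 1661 of 1739 peaks were higher in the ChIP library by the exact binomial test.

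**Figure D4:**
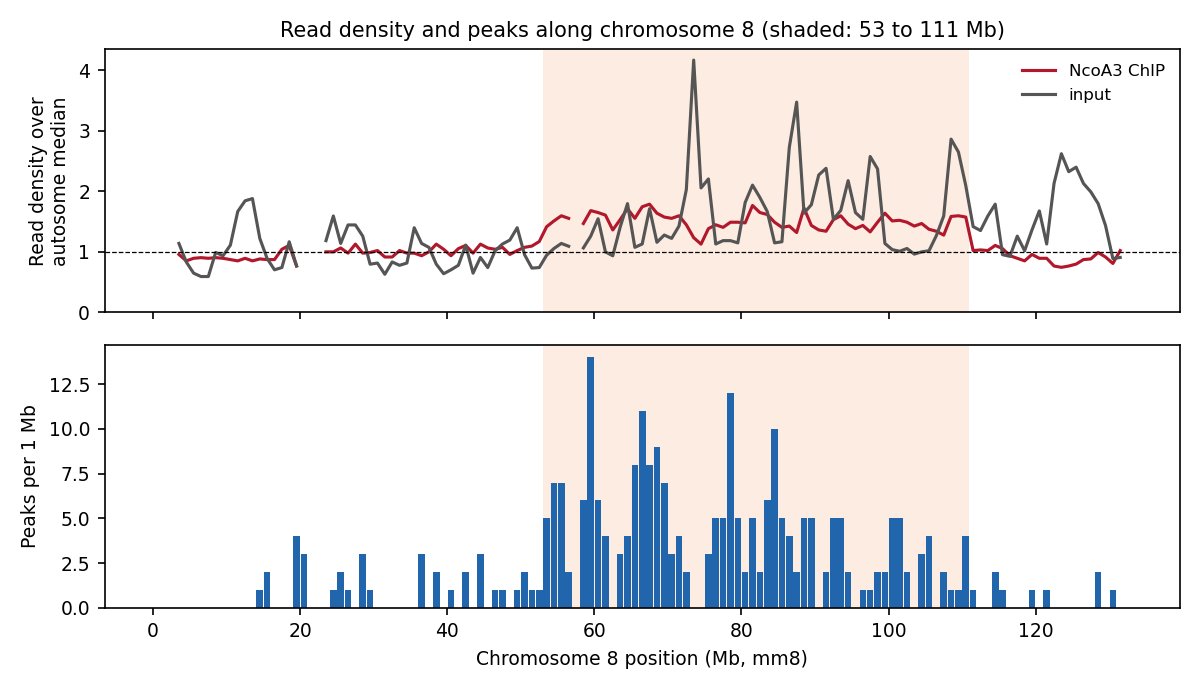
Upper panel, read density of the ChIP library (red) and the control (grey) in 1 Mb steps along chromosome 8 of mm8, over the autosome median; lower panel, number of peaks per Mb. In the shaded stretch, where 233 of the 278 peaks lie, density outside peaks over that of the other autosomes is 1.49 in the ChIP library and 1.10 in the control in the first part, and 1.45 and 1.55 in the second.

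The last comparison covered 1 kb bins outside the peaks. Of 150057 bins with 10 or more ChIP reads, 17175 were enriched over the control in the one-sided exact binomial test, at 4-fold or more. Their median count was 11 ChIP reads against 2 control reads, and no bin held more than 24 ChIP reads. With each bin scaled by the 100 kb around it, 1818 bins were enriched. The swapped comparison was run over all bins, peaks included, and called 50494 of 428911 bins as higher in the control. Over all bins, the ChIP library was higher in 17810 of 152710. When the reads of each bin were reassigned to the libraries by chance, 10 draws gave 0 bins in either direction. Coverage of 1 Mb blocks of the autosomes varied more in the control (SD 0.449 of the autosome median over 2364 blocks) than in the ChIP library (SD 0.138).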

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

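Many bins differed between the libraries outside the peak list, and most of them no longer passed once each bin was scaled to its surroundings. The bounds of the chromosome 8 stretch, the thinning of its reads with its reference and the comparison of its strong and weak peaks were chosen after values had been seen, as was the count of bins with local scaling.

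Outside the peaks, 17175 bins of 1 kb were enriched in the ChIP library over the control, and 1818 with each bin scaled by the 100 kb around it. Over all bins, peaks included, 17810 were enriched in the ChIP library and 50494 in the control, against 3487 and 7614 with that scaling. Reads reassigned by chance gave 0 bins in 10 draws, which covers counting noise but not regional differences in coverage. The most extreme control-enriched bin by adjusted p was 39451001 to 39452000 of chromosome 17, with 1326 control and 214 ChIP reads.

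The swapped count bears on the authors' false discovery rate, which stands at 100% for 2014 of the 2017 peaks in the authors' deposited table and under 5% for 1. A few extreme control regions are argued against, since the 50 largest clusters held 4.59% of the control-enriched bins. A broad difference in regional coverage between the libraries stays possible for most of these bins, since scaling each bin by its own 100 kb ended 85.9% of them. That 100 kb included the bin itself and its neighbours, so local enrichments could have been ended too. The same scaling also took the ChIP-enriched bins from 17810 to 3487. An excess of control bins at equal depth remained after it, so regional coverage is not shown to account for that excess. Local enrichments in the control also stay open, because its 50494 bins exceeded the 17810 enriched in the ChIP library, although these were 11.8% and 11.7% of the bins tested, and at equal depth the counts were 53013 and 6834, or 9919 and 1250 with local scaling. No biological explanation was tested, since the design has no group for it, and whether the control was input or IgG stays open.

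The excess of peaks on chromosome 8 lay in the stretch at 53000001 to 111000000, where all 4 quartiles were denser than on the other autosomes (2.61, 4.87, 7.005 and 7.21 times from strongest to weakest). An equal excess at every strength is argued against, since the interval of the strongest (1.74 to 3.78) lay below the 7.11 times of the 2 weaker quartiles together. Low control coverage as the whole cause is argued against in both parts, where peaks were 7.28 times (first part) and 3.44 times (second part) as dense as in 1 Mb blocks elsewhere with a matched ratio of the libraries, though in the first part, where that ratio was 1.35, it stays open as a contribution. Higher read density that lifts weak sites and an excess of weak sites cannot be told apart. Windows of 600 bp with 13 or more reads stood at 6.19 times the rate of the other autosomes. After the ChIP reads of the stretch were thinned to the density elsewhere, they stood at 0.688 times that rate. Of the 549 windows, 264 sat at the limit of 13 reads, so thinning removes many under either explanation. Thinning kept 11.03% of them, against 11.02% of windows elsewhere drawn to have the same read counts. The kept share depends only on those counts, so this match was fixed in advance and bears on neither explanation. Over the whole stretch, with the blocks between its parts counted, density was 1.45 times that of the other autosomes in both libraries. In the control it was 1.10 times in the first part and 1.55 times in the second, so extra copies of the stretch stay an untested hypothesis.

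The stretch was bounded at first as its second part alone, at 75000001 to 111000000, and the part at 53000001 to 73000000 was joined to it later. A first test of low control coverage used the ratio of the libraries itself, which was 0.936 in the second part, and was replaced by the matched blocks at that point. The matched blocks had not been seen when their bounds were set.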

How the results depend on the processing

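Of the settings below, the local 100 kb scaling, the header's tag totals, the list without peaks of 50 or more control reads, the list without chromosome 8, the stricter part of the list for chromosomes and the bins 2 kb from any peak were chosen after the data were seen. No result changed direction. The pooled ratio of 3.62 became 4.37 within 250 bp of the summit, 3.14 with the median ratio of 10 kb bins, 4.10 with the header's tag totals, 3.22 with the local scaling and 4.33 without peaks of 50 or more control reads. The ChIP share of 0.385% became 0.293% near the summit, 0.255% in the stricter part of the list, 0.377% with 5′ ends not moved and 0.348% without the peaks rich in control reads. The control share of 0.107% became 0.0671%, 0.0707% and 0.0805% near the summit, in the stricter part and without those peaks. Near the summit, in the stricter part and without those peaks the shares fell because fewer bases or peaks were counted, while for the other changes the cause was not tested. The count of 1923 peaks was 998 of 1010 in the stricter part, by its construction, and 1488 to 1982 in the other settings over the whole list. The excess on chromosome 8 was 2.75 with chromosome lengths and 1.73 in the stricter part. Of the chromosomes with fewer peaks, X and 7 still passed with lengths but 11 and 5 did not, and in the stricter part only 7 did. The read density of chromosome 8 was 1.17 times the autosome median in the ChIP library instead of 1.22 in the control. Enriched bins outside peaks fell from 17175 to 1751 at 8-fold and to 1818 with the local scaling, and were 17082 at 2 kb or more from a peak. The 20 pseudocount values of the named peaks kept their direction, which pseudocounts this small could hardly have reversed. Of the other values for the main comparisons, 18 were classed as unchanged by the limits set for each and 16 as moved, all with the same direction. In simulated counts at this depth with 200 changes, 33 of 67 true 4-fold changes were called, while on the real list no peak above 2.89-fold failed the test. Far more peaks passed on the real list than were changed in the simulation, so the simulated share called does not describe that list. The planned gene, start-site and motif comparisons were not run, nor was 1 read per position, which the deposited reads already have. No paired analysis was possible because each group has 1 library.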

Other observations

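The called peaks lay close together more often than positions drawn from control reads did. The spacing and its distance, the clusters named and the comparison of chromosome 6 with chromosome X were all chosen after values had been seen, the spacing at a longer distance. Of 2017 peaks, 141 had the next summit within 10 kb, against a mean of 25.1 and a maximum of 42 in 1000 sets of positions drawn from control reads on the same chromosomes (one-sided permutation p = 0.001, the smallest these sets can give). The strongest quartile had 32 such neighbours against a random mean of 1.41, and the weakest had 8 against 1.69. Without chromosome 8 the count was 126 against 16.9. It was not repeated without the peaks rich in control reads, so their part in this excess is unknown. There were 19 clusters of 3 or more peaks, and several were rich in reads of both libraries: the 6 peaks at 80491022 to 80509027 of chromosome 5 were 2.66-fold higher in the ChIP library, and the 4 at 3029983 to 3036757 of chromosome 9 were 1.21-fold higher.

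Around the summit, plus-strand ChIP reads lay mostly to the left and minus-strand reads mostly to the right. Across quartiles, 70.8% to 74.7% of reads lay on those sides. The caller had placed the summits on the ChIP reads, so this offset follows in part from that choice. The medians of the strands were 133 bp apart in the strongest quartile, 144 bp in the second, 163 bp in the third and 141 bp in the weakest.

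Read density over 12 Mb of chromosome 6, from 72000001 to 84000000, was 0.511 times the autosome median in the ChIP library and 0.389 times in the control, against 0.979 and 1.20 in the 10 Mb to each side. Missing or unmappable sequence is argued against, because 1 kb bins without a read in either library were only 2.13 points more frequent there than in the rest of the chromosome (6.87% against 4.74%). A single copy of this stretch in the cells behind both libraries is consistent with the values: its density differed by at most 0.0213 from that of chromosome X (0.532 in the ChIP library and 0.407 in the control). The single-copy reading assumes male cells with 1 chromosome X, which the labels do not state. Chromosome Y did carry reads, at 0.503 times the autosome median in the ChIP library and 0.350 times in the control. These chromosome Y values are per covered kb, a different scale from the 1 Mb medians. The stretch held 5 peaks. These data hold no other sample of the line, so whether the change is shared by other E14 cultures stays open.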
